A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

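Halobacterium salinarum NRC-1, an archaeon of saturated brines, was grown in complex medium to mid-log phase and kept for 5 h with 0, 0.2, 0.3 or 0.5 mM cobalt sulfate (CoSO4), per the labels' protocols. Total RNA of each of the 4 samples was hybridised on 2 arrays against one standard mid-log reference RNA of the same strain. The sample carried Alexa 532 on one array, named replicate 1 of its group here, and Alexa 647 on the other, named replicate 2. Both arrays of a sample held the same RNA extracts, so their mean was 1 replicate and n was 4 RNA samples. Nothing in the labels told of a repeated culture at any dose. The p-values therefore rest on the scatter of 4 samples around a line, with the spread of each feature drawn toward that of all features. A difference between single cultures has no repeat that would show it.

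The deposited values were treated as a score: the authors gave 1 number per spot and array, below and above 0, and the scanner, the background correction, the normalisation, the base of the logarithm and the numerator dye are not given in the sources used here. The values were read as log ratios of an unknown base and are printed in deposited units. The medians of the control arrays were 0.121 in Alexa 532 and 0.104 in Alexa 647. In the same order they were 0.0548 and 0.102 at 0.2 mM, 0.0581 and 0.123 at 0.3 mM, and 0.0788 and 0.145 at 0.5 mM. Medians that differed this much marked the table as not centred, so each array was set to a median of 0. Plain deposited values, planned as the main form for a table already normalised, became an alternative. Intensities and background were not used here, so signal over background is unknown and the number of arrays limits the precision.

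The sign of the values ran by dye and not by sample. Each spot was printed again in a later part of the array, and the difference between both printings of a spot is technical. As deposited, this difference correlated across spots between the dye orientations of a sample at r = 0.797 in the control, 0.690 at 0.2 mM, 0.742 at 0.3 mM and 0.779 at 0.5 mM, where values turned by sample would have opposite signs. Spots are not independent replicates. The rule set beforehand would have read the correlation of the features themselves, 0.733, 0.620, 0.729 and 0.713 in the same order, as values running by sample. It was set aside, because a shared dye bias gives such a correlation too. Values of the Alexa 532 arrays were multiplied by minus one, which gives sample over reference if Alexa 647 was the numerator. Under the opposite reading every sign turns. Changes are therefore described as being on the side of cbiG, printed as positive, or on the opposite side, and not as rises or falls.

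Each array had 10752 spots, 4 for each of 2688 features. A value was missing at 992 spots of each Alexa 532 array and 831 of each Alexa 647 array. Exact zeros occurred only on Alexa 532 arrays, at 174 spots in the control, 937 at 0.2 mM, 1270 at 0.3 mM and 294 at 0.5 mM, mostly late in the print order, and were left out as failed spots. A spot entered an orientation only with a value on all 4 of its arrays, and a feature needed at least 2 such spots per orientation. This left 2304 features and removed 384. The platform's gene annotation named 532 probes of 133 features with 1 gene symbol each and none with several, and 130 named features were tested. All 133 symbols occurred in the RefSeq gene table of another strain of the species (assembly of strain 91-R6), of which no coordinates are given and only the order of genes was used. The other 2174 tested features are unnamed here.

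The dose trend was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the 4 sample means, with the dose in mM as a number. It leaves 2 residual degrees of freedom and is given as the fitted change from 0 to 0.5 mM. In each SE and p-value, eBayes drew the spread of a feature toward that of all features, with 15.0 prior degrees of freedom. They therefore mostly reflect the spread of all features and not that of the feature alone. Without an RNA sample the trend was fitted on 3 samples, leaves 1 residual degree of freedom and is scaled to the same range. Without the control or the 0.5 mM sample that range reaches beyond the doses fitted. Cobalt against control set 3 samples against 1, with the lone control assumed to vary like the others. Its spread came from cobalt samples at different doses and the spread of the control is unknown, so its p-values do not decide whether cobalt differed from the control. Benjamini-Hochberg adjusted p under 0.05 was the threshold. On data simulated for the dose trend with 2304 features, 200 of them changed in each run, a change of 0.1 was called for 18.3% of the changed features, 0.2 for 93.1% and 0.3 for 99.8%, and 0.392% of unchanged features were called. With 200 changed features the adjusted threshold is looser than with few, and the simulated errors were independent between features. These shares therefore do not give the power in the real data.

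Before the data were examined, 24 gene lists were fixed by symbol and product text. Product text was not used here, so members were matched by symbol, and the aminoacyl-tRNA synthetases were listed by symbol afterwards. Lists with at least 5 tested members, 6 in all, entered limma's camera test with a preset correlation of 0.01. A minimum of 3, which let in the cobalamin list, was added after the data were seen. A list's mean change was also set against 10000 random lists of as many named features, as a description of these arrays. With 1 RNA sample per dose there was no test per dose. A feature counted at a dose if both orientations averaged a difference of 1 or more from the control, and 0.5 or more in each, with 0.30 and 0.15 added for a base of 10.

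The genes named were chosen by a rule fixed beforehand. Since fewer than 10 features passed, these were the 10 named genes with the smallest p on each side, said not to pass where they did not, up to 4 members of each list, and a preset group of which dpsA, phoU and arcA were tested. At most 2 unnamed features per side are given by spot number, apart from feature_2237, which is mentioned only in a tally by position. Alternatives were other centring and scaling, single orientations, all 8 arrays with or without the RNA sample as a random block (statmod 1.5.0), the median over spots, filters on orientation agreement, another variance model, each array or RNA sample left out, and the dose as rank. An array left out was replaced by the other array of its sample plus the mean difference between orientations in the other samples. Such a fit still held 4 sample means, and 1 of them drew partly on arrays of other doses. Keeping exact zeros, the agreement filter at 0.30, levelling each array by a running median over 129 spots and leaving the sign of the arrays unturned were added after the data were seen. The zero handling, the centring and the turning of arrays were also settled after the values, and counts under several of these settings, had been seen.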

Results

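The series measured RNA levels in Halobacterium salinarum NRC-1 after 5 h with cobalt sulfate on 8 arrays. The control without cobalt, 0.2 mM, 0.3 mM and 0.5 mM had 1 RNA sample each, hybridised in both dye orientations against a common mid-log reference, and 2304 features were tested, of which 130 carried a gene name. Values are centred differences in deposited units. Positive values mark the side on which cbiG changed, and whether that side is higher or lower RNA is not settled.

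The first question was which genes changed with the cobalt dose. The clearest named change was in cbiG, an enzyme that builds the corrin ring of cobalamin, the cofactor that holds cobalt (vitamin B12). Its fitted change from 0 to 0.5 mM was 0.229 ± 0.0428 (SE, n = 4 RNA samples; limma adjusted p = 0.0227). It differed from the control by 0.0845 at 0.2 mM, 0.201 at 0.3 mM and 0.215 at 0.5 mM. The change would be 1.70-fold if the values were logarithms to base 10 and 1.17-fold to base 2. The other 3 named and tested genes of the cobalamin list lay on the same side without passing the test. Any members among the unnamed features are not counted. These were cobN (0.161 ± 0.0388, adjusted p = 0.109), a subunit of the chelatase that inserts cobalt, cbiT (0.162 ± 0.0435, adjusted p = 0.212), a methyltransferase of corrin synthesis, and cbiQ (0.0539, adjusted p = 0.862), a membrane part of a cobalt transporter. In 6 comparisons of a cobalt array with the control array of its orientation, cbiG, cobN and cbiT were on this side in all 6 and cbiQ in 5. These comparisons share 1 control array per orientation and are not independent, and 112 of all 2304 features (4.86%) were on this side in all 6. Both cobN and cbiT passed as deposited (adjusted p = 0.0109 and 0.0115), among the 1083 features whose orientations agreed within 0.30 (0.00192 each), without the control array in Alexa 532 (0.0268 and 0.00528) and without the 0.2 mM sample (0.00205 and 0.00155). Values as deposited shift all features by the same amount, and both genes were at 0.198 there. The filter at 0.30 was set on uncentred values and removed cbiG and cbiQ. Neither cobN nor cbiT passed without a 0.2 mM array (adjusted p = 0.857 and 0.885 in cobN, 0.738 and 0.9998 in cbiT). Nor did they pass without the 0.3 mM array in Alexa 647 (0.997 each), the control sample or the 0.5 mM sample. Without a 0.5 mM array cobN passed for Alexa 647 (0.0214) and cbiT for Alexa 532 (0.0328). Without the control sample the change of cbiT was 0.0418, and without the 0.5 mM sample 0.278, each a slope extended beyond the doses fitted. The change of cbiG was between 0.190 and 0.318 in all settings that turned the arrays, but its call was lost in 12 of 26 settings, among them no array turned (-0.0398, adjusted p = 0.869), quantile normalisation (adjusted p = 0.105), the Alexa 532 arrays alone (0.664), kept zeros (0.0633), levelling (0.0824) and 8 arrays without a block (0.0606). It was also lost without the control array in Alexa 647 (adjusted p = 0.278), the 0.2 mM array in Alexa 532 (0.133) or Alexa 647 (0.540), the 0.3 mM array in Alexa 647 (0.997), the control sample (0.805) or the 0.5 mM sample (0.108).

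Of the 4 cobalamin genes, 1 passed over all features and 3 passed adjusted over the list alone. Their mean change was 0.152, above all 10000 random lists of 4 named features, and their mean difference from the control was 0.0852 at 0.2 mM, 0.130 at 0.3 mM and 0.149 at 0.5 mM. The list was below the planned minimum size, and once lists of 3 or more were admitted it was the single list of 9 called by camera (adjusted p = 1.46e-06). That call was lost with an estimated correlation (adjusted p = 0.583), and limma's fry gave an adjusted p of 0.400. The mean was 0.176 on the Alexa 532 arrays and 0.128 on the Alexa 647 arrays, and without the control sample it was 0.0974. With no array turned it was -0.0239, so the result rests on the reading of the dyes.

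**Figure D1:**
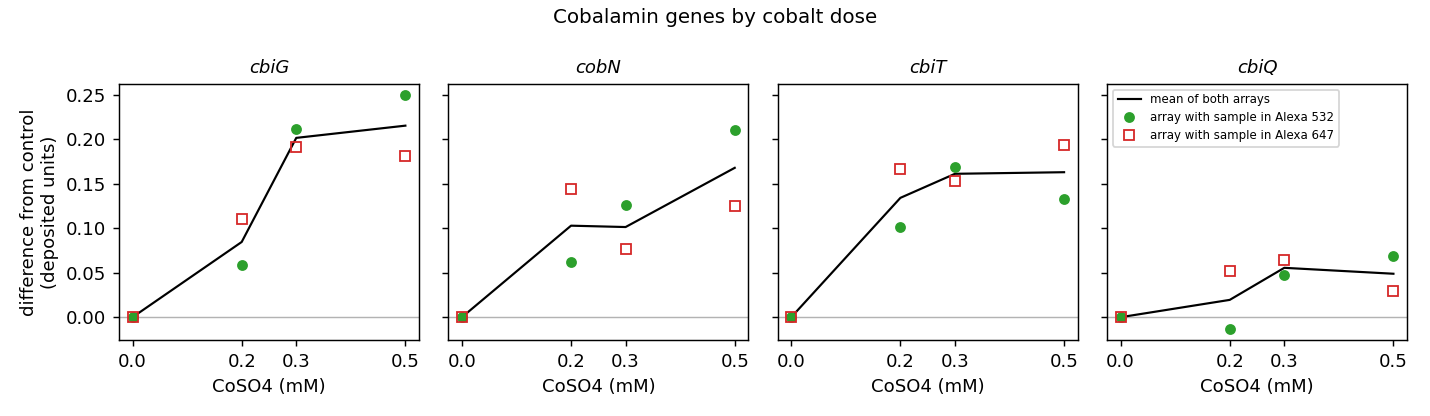
Difference from the control (deposited units, vertical) against the CoSO4 dose in mM (horizontal) for cbiG, cobN, cbiT and cbiQ. Circles are arrays with the sample in Alexa 532, squares those with it in Alexa 647, each minus the control array of its orientation, and lines join their means, which reach 0.215 in cbiG and 0.168 in cobN at 0.5 mM; all points above 0 mM lie above the control except cbiQ at 0.2 mM in Alexa 532.

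In all, 9 features passed the dose trend, all on the side of cbiG and none on the opposite side, and 184 had an unadjusted p under 0.05 where 115.2 would be expected by chance. The number with no array turned, where effects of the sample cancel, was also 184, so the excess over chance does not point to the dose. Besides cbiG the 8 others were unnamed. Of the 9 features 8 lay at the same 1 in 4 positions of the print order, as did cobN, cbiT and 573 of the 2304 tested features in all. Of the features with an unadjusted p under 0.001, 10 lay at these positions and 4 elsewhere. These 10 were the 8 passing features there, cobN and feature_2237. The last of them lies between spots 2197 and 2302, as do 6 of the 8. The tally is therefore no separate evidence of an effect of position. The changes of the features at spots 2197 and 2293 were 0.263 ± 0.0409 (feature_2197, limma adjusted p = 0.00842) and 0.252 ± 0.0398 (feature_2293, the same adjusted p). On the opposite side the smallest p belonged to feature_3455, at -0.290 (adjusted p = 0.0596), and feature_1007, at -0.228 (adjusted p = 0.0596), which did not pass. The count was 26 on the values as deposited (24 on the side of cbiG, 2 opposite), 14 on arrays scaled to one spread (12 and 2), 0 after quantile normalisation, 0 on the Alexa 532 arrays, 50 on the Alexa 647 arrays (7 and 43), and 10 with no array turned, 0 of them shared with the 9. Without one array it was 0 for the control or the 0.3 mM array in Alexa 647 and for either 0.2 mM array, 41 and 62 for the 0.5 mM arrays in Alexa 647 and Alexa 532, and 68 for the control in Alexa 532; without a whole RNA sample it was 3 for the control, 42 for 0.2 mM and 3 for 0.5 mM.

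**Figure D2:**
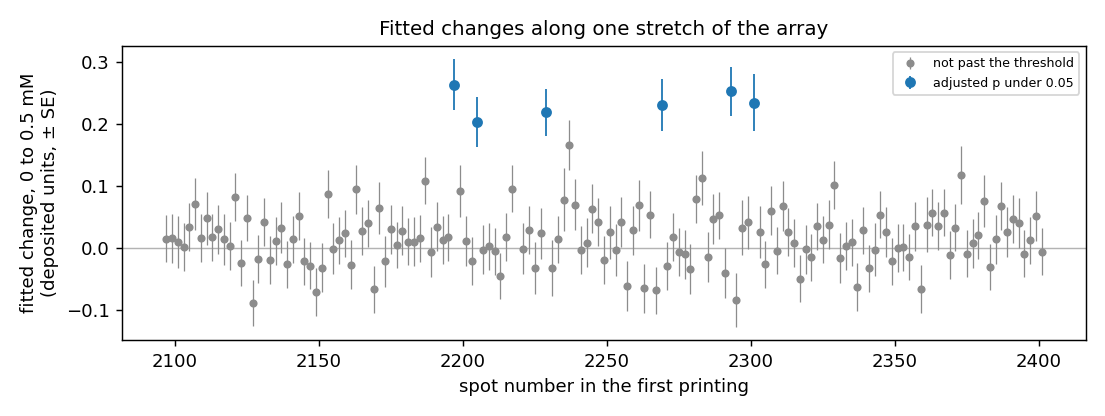
Fitted change from 0 to 0.5 mM CoSO4 (deposited units, vertical, bars ± SE) of neighbouring features against their spot number in the first printing (horizontal). The 6 blue features that passed lie at 0.203 or more between spots 2197 and 2302, and the grey features between them at 0.166 or less.

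Named genes with the next smallest p on the side of cbiG did not pass the test. They included pyrI, the regulatory subunit of aspartate carbamoyltransferase in pyrimidine synthesis (0.109 ± 0.0379, limma adjusted p = 0.398), and folP, the dihydropteroate synthase of folate synthesis (0.103), with 0.182 on the Alexa 532 arrays and 0.0240 on the Alexa 647 arrays. The arginine fermentation genes arcA (0.114), the arginine deiminase, and arcC (0.0980), the carbamate kinase, lay on this side together. They lie close together in the print order, at spots 2655 and 2687, after pyrI at spot 2623. Levelling over that order left 0.110 in arcA and 0.105 in arcC. Neither passed over all features, and both passed adjusted over the list alone. Their mean of 0.106 was at percentile 98.5 of random pairs of named features, which were not matched on such closeness. Most of this came from the Alexa 532 arrays, with 0.191 against 0.0367 on the Alexa 647 arrays in arcA and 0.145 against 0.0506 in arcC, and arcA was at 0.0321 without the 0.5 mM array in Alexa 532. Without the one in Alexa 647 arcA passed at 0.196 (adjusted p = 0.0427), and without the control sample it was at 0.195. The phosphate uptake regulator phoU was at 0.138 ± 0.0541, but at -0.0814 at 0.2 mM and 0.109 at 0.5 mM, and at 0.278 without the control sample (adjusted p = 0.136). It passed without the control array in Alexa 532 (0.149, adjusted p = 0.0344) and among features whose orientations agreed within 0.30 (adjusted p = 0.0119). The histidyl-tRNA synthetase gene hisS was at 0.0957, with 0.172 on the Alexa 532 arrays and 0.0190 on the Alexa 647 arrays. The purine synthesis gene purL differed from the control by 0.0955 at 0.5 mM, and its fitted change turned its sign with the median over spots.

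On the opposite side, pyrB, the catalytic subunit of aspartate carbamoyltransferase, had a fitted change of -0.227 ± 0.0761 (limma adjusted p = 0.394). It came from 1 orientation, with -0.460 on the Alexa 532 arrays and 0.00544 on the Alexa 647 arrays. It was 0.125 without the control sample and 0.0382 without the control array in Alexa 532, and it passed at 0.232 with no array turned (adjusted p = 0.00150). With the arrays turned it passed at -0.580 without the 0.5 mM sample (adjusted p = 8.83e-06), at -0.253 without the 0.2 mM sample (adjusted p = 6.03e-08) and at -0.253 without the 0.5 mM array in Alexa 647 (adjusted p = 0.0214). The value of -0.580 extends a slope over 0 to 0.3 mM, and fits without an RNA sample leave 1 residual degree of freedom. The gene dpsA, for an iron-storing DNA-binding protein, was at -0.115 ± 0.0389 (adjusted p = 0.394), with 0.0538 at 0.5 mM in Alexa 532 and -0.265 in Alexa 647. Likewise hemA, for the glutamyl-tRNA reductase that opens tetrapyrrole synthesis, was at -0.108 (adjusted p = 0.398), with 0.00879 and -0.231. Both passed on the Alexa 647 arrays (dpsA -0.280, adjusted p = 0.00116; hemA -0.228, 0.0107), without the control array in Alexa 532 (0.00533 and 0.0157) and without the 0.5 mM array in Alexa 532 (0.00870 and 0.0224), and without the one in Alexa 647 they were at 0.0262 and -0.00888. More even between orientations were lysS (-0.111), the lysyl-tRNA synthetase gene, with -0.104 and -0.0966 at 0.5 mM, gatA (-0.0956), for a subunit of a tRNA amidotransferase, and sop2 (-0.0864), sensory rhodopsin II. The remaining genes were hisI (-0.0891) of histidine synthesis, purM (-0.0868), thrS (-0.0744) and htr2 (-0.0733). Of these, hisI passed on the Alexa 647 arrays (adjusted p = 0.0485), and hisI and htr2 passed without the 0.5 mM array in Alexa 532 (0.0227 and 0.0475) and turned to 0.0152 and 0.0212 without the one in Alexa 647. On the Alexa 532 arrays alone, dpsA, hemA, hisI and htr2 lay on the side of cbiG.

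The gene lists asked whether groups of genes shifted along the dose. None of the 6 lists of 5 or more genes was called by camera, with adjusted p of 0.491 for 5 of them and 0.930 for nucleotide synthesis, and between 0.769 and 0.935 with an estimated correlation. No member of these lists passed over all features or adjusted over the list alone. Of the 5 citrate cycle genes 4 were on the side of cbiG, led by citZ (0.0713), citrate synthase, and icd (0.0610), isocitrate dehydrogenase. Of the 11 chemotaxis and transducer genes 8 were on the opposite side, from htr2 to cheY (0.0639) at the other end. As deposited, all changes lay further to the side of cbiG by the same amount. That turned most of these 8 and some opposite genes of the lists below. Among the 6 DNA repair and replication genes the largest changes were in uvrA (-0.0376) and radB (-0.0315), and the sign of radB turned on values as deposited. Amino acid synthesis had 7 of 10 genes on the opposite side, with hisF at -0.0616. Nucleotide synthesis was split 5 and 5 and held both pyrB and pyrI, while 7 of the 12 aminoacyl-tRNA synthetase genes were on the opposite side.

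Smaller groups, apart from the cobalamin list, held no gene that passed over all features. Adjusted over the list alone, dpsA and phoU passed, each as the 1 tested member of its list. The 4 protein quality control genes lay between -0.0364 (dnaJ) and 0.0275, and the 4 phototrophy genes between -0.0864 (sop2) and 0.0296. The ribosomal protein genes rpmC and rpl12p were at -0.0561 and 0.0467, the respiratory chain genes sdhC and nuoL at -0.0296 and -0.00561, and msrA, a methionine sulfoxide reductase, at -0.0568. The signs of dnaJ, psmA, sdhC, nuoL and sop1 turned on values as deposited. No tested feature carried a name from the other 9 lists, which were metal transport, iron-sulfur cluster assembly, RNA polymerase, gas vesicles, ATP synthase, the archaellum, general transcription factors, transposases and peptide transport.

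**Figure D3:**
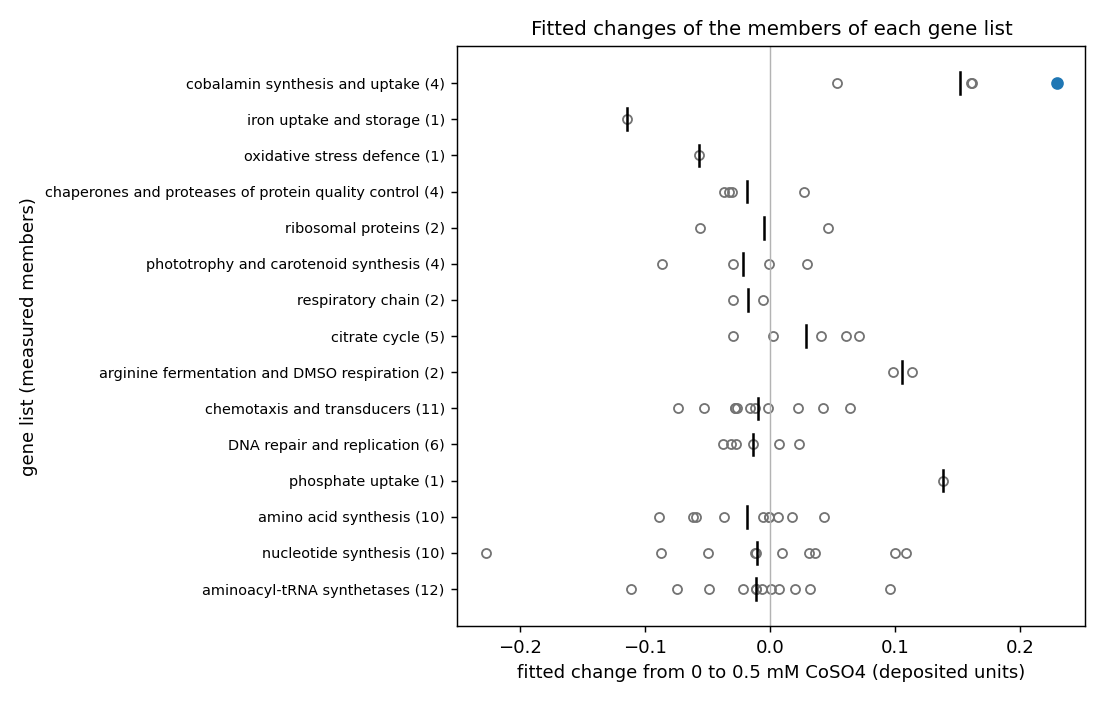
Fitted change from 0 to 0.5 mM CoSO4 (deposited units, horizontal) of each tested member of the gene lists (vertical, with the number of members). Open circles did not pass the test, the filled circle is cbiG, and bars are list means; the cobalamin mean of 0.152 lies to the right of the other means.

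The next comparison set the 3 cobalt samples against the control. With 1 control sample, and a spread taken from samples at 3 different doses, the planned limma test cannot tell whether cobalt differed from the control, and its counts are given as a description. It called 0 features, and 61 had an unadjusted p under 0.05, fewer than the 115.2 expected by chance, 42 on the side of cbiG and 19 opposite. The difference from the control was -0.283 in pyrB, again from the Alexa 532 arrays, 0.167 in cbiG, 0.153 in cbiT and 0.124 in cobN. The count was 11 on values as deposited, 13 without the control array in Alexa 647 and 33 without the 0.2 mM sample.

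No feature met the size rule at any dose, at a difference of 1 or at 0.30. Against the control, differences ranged from -0.288 (pyrB) to 0.252 at 0.2 mM, from -0.334 (pyrB) to 0.231 at 0.3 mM and from -0.252 to 0.250 at 0.5 mM. None met it between neighbouring doses or between the control and the reference, where values ranged from -0.382 to 0.259. Turned the same way, the orientations of a sample shared little across all features, with r between their differences from the control of 0.139 at 0.2 mM, -0.00565 at 0.3 mM and -0.0641 at 0.5 mM, over features that are not independent replicates.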

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

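Keeping exact zeros, levelling, no array turned, the filter at 0.30, the base-10 thresholds and lists of 3 or more were chosen after the data were seen. The cobalamin mean lay above the central 95% of random lists in 26 of 27 settings (0.0974 without the control sample to 0.216 without the 0.5 mM sample, both extended beyond the doses fitted). The other variance model, the filter at 1 and the 8 arrays with or without a block left the fitted changes of these genes as they were. The filter at 0.30 kept 2 of the 4 genes. With no array turned it was -0.0239, and cbiG was at -0.0398, as the construction of that setting removes effects that follow the sample. Of 26 settings with a value for cbiG, 14 kept its call and 12, the unturned one included, ended it, with changes of 0.190 to 0.318 and adjusted p of 2.79e-06 to 0.997 outside the unturned setting. Of 34 named genes over 905 gene and setting pairs, 850 kept their sign, 9 genes gained a call in some setting, and leaving out 1 RNA sample moved 22 of the 34 by over 1.5 times and turned 3. Part of the kept signs was fixed beforehand, since another variance model, a filter or a block does not alter a gene's fitted change.

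The number of features passing the dose trend (9 on the side of cbiG, 0 opposite) became 26 as deposited (24 and 2), 0 after quantile normalisation (0 on the side of cbiG), 14 with scaled arrays (2 opposite), 0 on Alexa 532 arrays (0 on the side of cbiG), 50 on Alexa 647 arrays (43 opposite), 10 with the median over spots (1 opposite), 35 with orientations within 0.30 (21 and 14), 12 with trend and robust (3 opposite), 15 with dose as rank (2 opposite), 3 with zeros kept (2 and 1), 2 levelled (2 and 0), 10 unturned (1 and 9) and 3 with 8 arrays and no block (3 and 0). Without an RNA sample it was 3 for the control (2 and 1), 42 for 0.2 mM (32 and 10), 12 for 0.3 mM (3 opposite) and 3 for 0.5 mM (1 and 2). Leaving out single arrays gave 0 (control in Alexa 647) to 68 (control in Alexa 532), with 0 to 39 on the side of cbiG and 0 to 52 opposite. Of the 35 features within 0.30, 3 were among the 9, and that filter removed cbiG. The cause of the changed counts was not tested. The random block of the RNA sample gave 10; its estimated correlation was -0.258.

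Cobalt against control, 0 features, became 11 as deposited, 1 after quantile normalisation, 2 with the median over spots, 33 without 0.2 mM, 1 without 0.5 mM, 1 levelled, 1 unturned and 0 to 13 over single arrays left out. Gene lists stayed at 0 calls in the settings run for them, except 1 with lists of 3 or more, and the random block could not be used in that test. They were not run with the median over spots, the orientation filters, another variance model, the dose as rank, kept zeros, levelling or unturned arrays. At the base-10 thresholds the size rule gave 0 features per dose, and with thresholds lowered to 0.17 and 0.09 it gave 2, 9 and 12 at 0.2, 0.3 and 0.5 mM. On Alexa 532 arrays it gave 6, 3 and 5, on Alexa 647 arrays 1 at 0.3 mM and 4 at 0.5 mM, and over single arrays left out 0 to 5, 0 to 4 and 0 to 3. The cause of these shifts was not tested. No paired analysis was possible because each dose had 1 RNA sample.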

Other observations

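Every test below except that of the 2 printings was chosen after the results had been seen, as were the genes of the next paragraph.

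Both sensory rhodopsins and their transducers lay on the side opposite to cbiG, with fitted changes of -0.0297 in sop1, -0.0530 in htr1, -0.0864 in sop2 and -0.0733 in htr2, and none passed the test. As deposited sop1 was at 0.00688, and on the Alexa 532 arrays htr1 was at 0.00828 and htr2 at 0.0411. The 4 genes lie close together in the print order, and levelling over it left -0.00905 in sop1, -0.0233 in htr1, -0.0521 in sop2 and -0.0408 in htr2. Genes of other cofactor pathways did not pass either. The molybdopterin genes moaA (-0.0555) and moaC (-0.0624) were on the opposite side in both orientations, and the thiamine gene thiL was at 0.0786. The thiamine genes thiD (-0.0555) and thiC (-0.0109) opposed between orientations, at 0.0600 and 0.110 on the Alexa 532 arrays and -0.171 and -0.132 on the Alexa 647 arrays, and thiC was at 0.0258 as deposited and 0.00696 levelled.

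In the dose trend 9 features passed. The real order of the 4 samples over the doses was 1 of 12 distinct orders and gave all 9, and the highest other order gave 8; 12 orders are too few for a share under 0.05. A dye effect shared by both arrays of a sample cancels in their mean by construction. That 0 of the 9 passed with no array turned is therefore no further test of it. That setting cancels effects of the sample and holds errors of single arrays as strongly, and 10 features passed in it, so such errors could account for a count of this size.

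For the 4 cobalamin genes, the design and the values argue against several technical explanations. A dye effect shared by both arrays cancels in the mean of a sample by construction, so it cannot have given the mean change of 0.152. The mean of -0.0239 with no array turned is a separate contrast and does not test this. Signal that drifts along the print order would go with levelling, after which the mean was 0.142, above the central 95% of random lists (up to 0.0651). Levelling does not remove unevenness confined to 1 in 4 positions, so it does not test that. A single orientation was not the source, since the smaller mean of both was 0.128. A shift of all features at the 1 in 4 positions that cbiG, cbiT and cobN share was not found. The median change of those 573 features was 0.00306, and the cobalamin mean lay above all 10000 random lists matched on position. Matching on these positions does not match closeness in the print order or correlation between genes. As cbiG (spot 469) and cbiT (spot 509) lie near each other, the random lists do not argue against a local error. Of the 9 features that passed, however, 8 lay at those 1 in 4 positions, cbiG among them. With an unadjusted p under 0.001 there were 10 there and 4 elsewhere. Those 10 were the same 8, cobN and feature_2237, so they are not separate evidence. Over single arrays left out the mean was 0.128 to 0.175, but the call of cbiG was lost without some of them. Errors of single arrays therefore stay open, as does an error of some features at these 1 in 4 positions. So do a difference between single cultures, since each dose had 1 RNA sample and the mean was 0.0974 without the control, and a response of cobalamin synthesis to cobalt, a hypothesis that was not tested.

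Of the 8 unnamed features passing the dose trend, 6 lay within 53 neighbouring positions of the print order, all at the same 1 in 4 positions. An error of the whole region was not found, as the median change of all its 52 features, these 6 included, was 0.0209 against 0.232, nor one of 1 printing, as the mean changes were 0.254 in the first and 0.212 in the second, a ratio of 0.833. An error tied to the 1 in 4 positions within the region stays open. The median of all 14 features there was 0.117, but it holds the 6 picked for passing, so it cannot decide. Of the 14, 9 were on the side of cbiG and 7 were under 0.1. The named genes hisS, cbiQ and thiL lay in the region at other positions. Among 4 further features of the region with an unadjusted p under 0.05 was hisS. Named genes within 10 genes of each other in the gene table of strain 91-R6 were often arrayed in this pattern. Of 104 such pairs 39.4% lay as close at the same 1 in 4 positions, against 0.954% of 8281 other pairs. That share was under the 50% set for the test, and the 6 features are unnamed. It therefore stays open whether they are neighbouring genes, and no biological explanation was tested.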
